A study of Rattus norvegicus with 12 samples.

How the data were processed

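RNA from rat iPS lines, ES lines and embryonic fibroblast cultures was measured on 12 Affymetrix single-colour arrays, with 4 arrays per cell type and 2 per line or culture. Per the labels' protocols, about 100 ng of RNA was amplified and biotin-labelled, iPS and ES cells were grown in 2i medium and fibroblasts in MEF medium. The deposited values are log2 signals of 31099 probe sets, and RMA and Partek 6.2 are named per the submitters' processing notes. RMA corrects background, normalizes between arrays and summarises the probes of each set, which compresses differences of dim genes and of genes near saturation. Whether all 12 arrays were normalized together is not given in the sources used here. The values lay between 1.45 and 14.12 and were used as deposited.

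Probe sets were named through the platform's gene table: 20832 had 1 gene symbol, 436 had several, 9831 were not listed and are unnamed here, and 57 of all probe sets were array controls. Of those with 1 gene, 20764 were matched by gene identifier to a gene table of the assembly GRCr8, and 0 symbols changed. The 14218 genes were each represented by the probe set with the highest mean over all arrays, and 4526 genes had more than 1 probe set. Genes whose highest cell type mean was under 5 were left out, which removed 3708 and left 10510.

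Groups were taken from the labels, and no array was moved to another group after its values were seen. Cell types were compared in limma 3.58.1 (R 4.3.3) with the line as a random block (consensus correlation 0.966), empirical Bayes moderation and Benjamini-Hochberg adjustment over the 10510 genes, with calls at adjusted p under 0.05. Lines were compared in a second limma fit with the 6 lines as the factor. A set of 24 gene lists was written down, of which 23 were tested. The test was camera on the moderated statistics at a preset correlation of 0.01, adjusted over 69 tests. An estimated correlation served as an alternative. For cell types with all arrays it was computed on line means. Between lines, and without the arrays labelled DAC8 and REF2, it was computed on single arrays. The arrays of a line were taken as independent there, so those adjusted p-values are not tests on line means. The list of sex chromosome genes served only as a check. Lists covered pluripotency, reprogramming, signalling, cell cycle, imprinting and chromatin genes and markers of fibroblast, epithelial, endoderm, mesoderm, neural, trophoblast, germline, blood, endothelial, muscle and skeletal cells.

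The genes named for each cell type comparison were the 10 called genes with the largest difference in each direction whose 4 arrays of one type all lay above the 4 of the other. To these were added up to 4 members of each list that passed or held a called member of at least 2-fold, and Sox2, Klf4 and Myc. For line comparisons they were the 5 called genes with the largest difference in each direction and any called sex chromosome gene. Levels of Postn, Esrrb, Epcam, Elavl4 and Sox2 per line were set side by side after the values were seen. Position between fibroblasts and ES cells was the projection of each array on the line from a fibroblast culture to an ES line, averaged over the 4 choices and scored only on axes its own line did not define.

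The groups, tests, lists, named-gene rule and most alternatives were fixed before the data were examined. Alternatives were no line block, line means, a replicate block, only the 2 cell types compared, no filter, a filter at 6, quantile normalization, a shift to equal medians, an intensity trend, the mean of probe sets, every probe set, and each array or line left out. Added after the data were seen were the fits without the arrays labelled DAC8 and REF2, the lists between lines, all pairs of lines and the single axis from REF1 to DAC2. The rule for reading the splits of arrays was also changed after their counts were seen: a share is read only from splits that keep lines whole and where the real count is over 0. The test of exchanged labels was likewise changed after its result, so that it can exclude an exchange but not support one.

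The fits were tested on simulated arrays of 10510 genes, of which 50 were changed at each size and the rest were left unchanged. The shares of false calls below depend on how few genes were changed. They are therefore not the shares among the genes called in the data. For iPS against EF, 14%, 56%, 92% and 100% of genes changed by 1, 2, 4 and 6 log2 units were recovered, and 54.4% of calls were false. With line means 0%, 18%, 52% and 70% were recovered, and 2.78% of calls were false. Where lines were simulated as alike as A1 and A2, 23.8% of block-fit calls were false (62 of 260), against 4.02% with line means (8 of 199). The same genes were changed for both fits, so the block fit called too readily on simulated arrays and line means did not. For A1 against A2, 92% of changes of 1 log2 unit were recovered. Correlations and positions were computed in R, and plots were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.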

Results

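Gene expression was measured on 12 single-colour rat arrays, 4 for each of 3 cell types. The arrays labelled iPS held 2 lines of induced pluripotent stem cells, A1 and A2, made from the FHH rat strain. The arrays labelled ES held 2 embryonic stem cell lines, DAC2 and DAC8, whose strain the labels do not give. The arrays labelled EF held 2 cultures of FHH embryonic fibroblasts, REF1 and REF2, prepared from embryos. Each line or culture had 2 arrays, and RNA was taken 5 days after passage from iPS and ES cells and 6 days after passage from fibroblasts. The labels mark iPS and ES cells as positive for SSEA-1, Oct4, Nanog and Sox2. They record growth of the iPS lines on mouse feeder fibroblasts and do not say whether feeders were removed. They also do not say whether the 2 arrays of a line came from separate cultures. The p-values between lines therefore measure only the spread between these arrays, which may be technical. With all 12 arrays, the p-values between cell types take in the spread between the 2 lines of a label only in part, through the line block (consensus correlation 0.966). The block used 1 correlation for all genes and kept 9 residual degrees of freedom with only 6 lines. These p-values can therefore be too small, and on simulated arrays this fit gave a larger share of false calls than line means. Array medians lay between 5.28 and 5.41 log2 units, and 53.6% to 54.6% of probe sets per array were at or above 5. A level below 5 was not shown to be above background, so a difference with 1 side below 5 is at best a lower bound on its size, and no order is read among such differences. The number of arrays limits the precision of every value.

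The arrays of each line were compared first, because the labels set the direction of every later comparison. The arrays labelled DAC8, an ES line, carried high levels of fibroblast genes, and the arrays labelled REF2, a fibroblast culture, carried high levels of epithelial and pluripotency genes. Postn, which encodes the matrix protein periostin, measured 13.61 ± 0.04 (log2 level, mean ± SD, n = 2) in DAC8 and 13.74 ± 0.04 in REF1, against 3.79 ± 0.29 in DAC2 and 3.45 ± 0.08 in REF2. Esrrb, a transcription factor of naive pluripotent cells, measured 10.28 ± 0.01 in DAC2 and 9.96 ± 0.03 in REF2, against 4.14 ± 0.21 in DAC8 and 4.56 ± 0.14 in REF1. Epcam, an epithelial adhesion molecule, measured 11.84 ± 0.06 in DAC2 and 11.55 ± 0.07 in REF2, against 2.85 ± 0.47 in DAC8, and was similarly low in REF1. The arrays labelled A1 and A2 were low for all 3 genes and held high levels of neuronal genes, such as Elavl4 at 10.70 ± 0.01 and 10.64 ± 0.03. Sox2, a factor of pluripotent and neural progenitor cells, measured 9.43 ± 0.04 in A1, 9.31 ± 0.08 in A2, 11.48 ± 0.06 in DAC2, 11.57 ± 0.05 in REF2, 4.79 ± 0.09 in DAC8 and 3.86 ± 0.27 in REF1. Pou5f1 and Nanog were not analysed here.

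**Figure D1:**
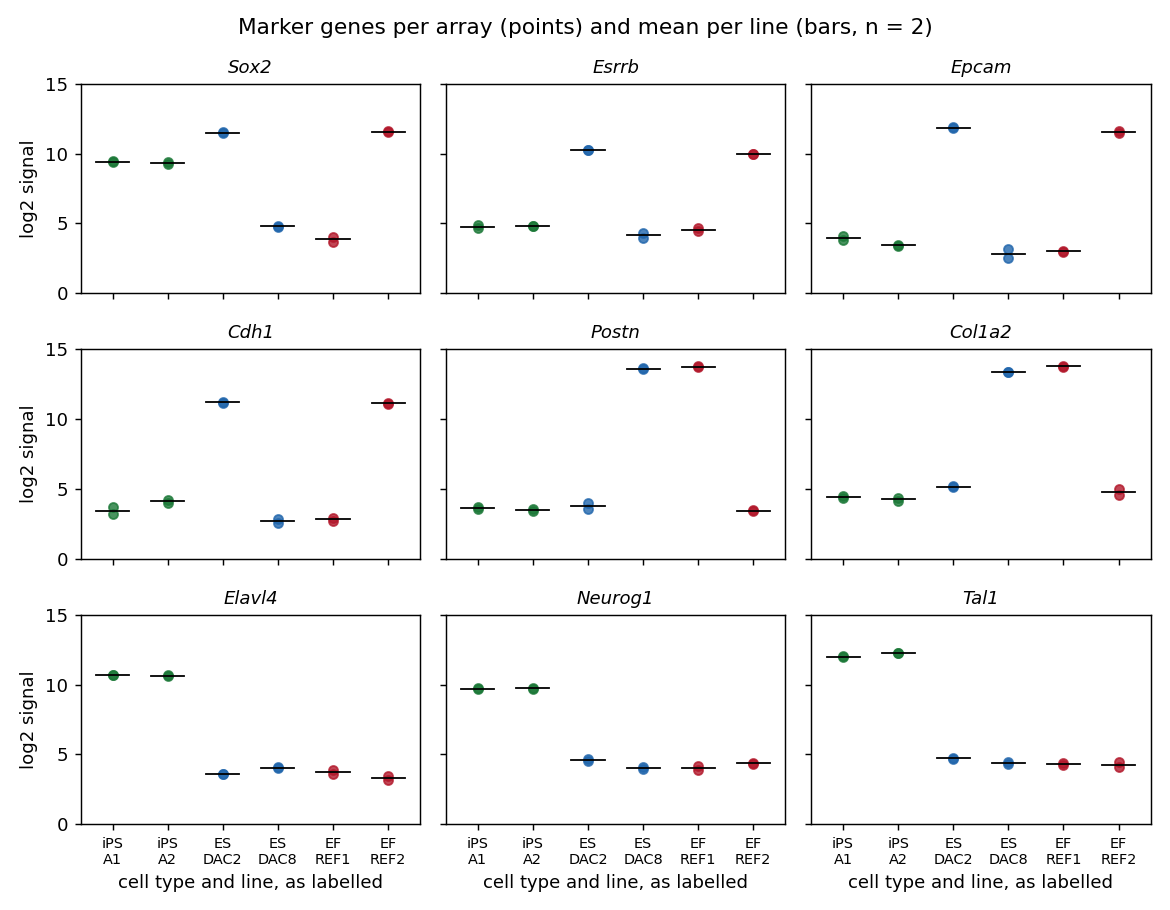
Log2 signal of 9 marker genes per array (points) and mean per line (bars, n = 2), with lines grouped by cell type as labelled. The arrays labelled DAC8 lie with REF1 near 13.61 for Postn, the arrays labelled REF2 lie with DAC2 near 11.55 for Epcam, and A1 and A2 stand above all other lines for Elavl4, Neurog1 and Tal1.

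Correlations across the 10510 tested genes followed the same arrangement. The mean Pearson correlation was 0.988 between arrays labelled DAC8 and REF1 but 0.614 between those labelled DAC8 and DAC2. It was 0.974 between arrays labelled REF2 and DAC2 but 0.612 between those labelled REF2 and REF1. A1 and A2 correlated at 0.994 with each other. A1 correlated at 0.735 with DAC2, 0.731 with REF2, 0.701 with DAC8 and 0.697 with REF1. Arrays of the same line correlated at 0.996 to 0.998, and genes are not independent replicates. The difference between the 3' and 5' probe sets of beta-actin, a sign of RNA quality and amplification, was 0.84 to 0.87 in iPS arrays and 0.88 in DAC2. It was 0.94 to 1.05 in REF2, 0.45 to 0.52 in DAC8 and 0.42 to 0.48 in REF1. No array was given another group, so each ES or EF mean below averages a line with a fibroblast profile and a line with an ES-like profile.

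**Figure D2:**
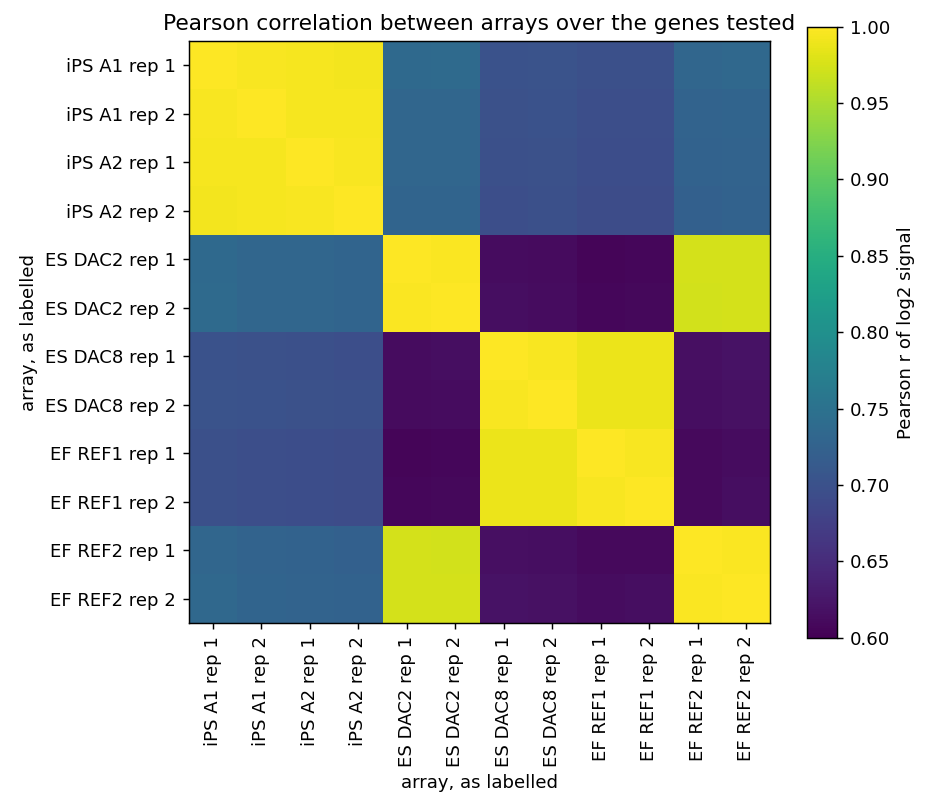
Pearson correlation of log2 signal between the 12 arrays over the 10510 tested genes, ordered by line, with cell types as labelled. The arrays labelled DAC8 and REF1 share high values near 0.988, as do those labelled REF2 and DAC2 near 0.974, and A1 and A2 form a block near 0.994.

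The comparison of iPS with EF arrays was to address what distinguished the iPS lines from fibroblasts of the same strain. The EF arrays labelled REF2 had an ES-like profile, so it is not a comparison with fibroblasts alone. Tal1, a transcription factor of blood and neural progenitors, was higher in the arrays labelled iPS by 7.82 ± 0.55 (log2 difference ± SE, 4 arrays against 4, limma adjusted p = 3.15e-05). Elavl4, a neuronal RNA-binding protein, was higher by 7.13 ± 0.56, Fez1, which acts in axon growth, by 6.97 ± 0.56 and Rtn1, a reticulon of neuronal cells, by 6.92 ± 0.56. Ccn2, a matricellular growth factor, stood at -8.31 ± 1.48 (adjusted p = 0.00661) and Klf2, a factor of the naive pluripotency network, at -7.13 ± 0.81 (adjusted p = 0.000421). The axon guidance gene Draxin differed by 6.78 ± 0.67, Gap43 by 6.71 ± 1.39, Mgst1 by 6.58 ± 0.61, Stra6l by 6.58 ± 0.78, Gpm6a by 6.42 ± 0.57 and Stmn3 by 6.41 ± 0.69. Lower in iPS, Cdh22 stood at -6.47 ± 0.79, Gask1b at -6.41 ± 0.88, Anxa3 at -6.33 ± 0.60, Tmem30b at -5.94 ± 0.89, Eci3 at -5.69 ± 0.73 and Myof at -5.63 ± 1.28. The imprinted RNA H19 stood at -5.47 ± 0.74 and Colec12 at -5.25 ± 1.11. Of these, Tal1, Elavl4, Fez1, Draxin, Stra6l and Gpm6a lay below 5 in all EF arrays and every lower gene but H19 in all iPS arrays. For Gap43 and Cdh22, 1 of 2 probe sets went the other way. In all, 562 of 10510 genes differed at adjusted p under 0.05, 341 higher and 221 lower in iPS, of which 561 differed at least 2-fold.

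Among the gene lists, 12 of the 17 tested neural genes rose in iPS against EF and 0 fell, and 14 rose when adjusted over the list alone (camera adjusted p = 5.1e-29; adjusted p = 0.158 with an estimated correlation). Neurog1, a proneural factor, differed by 5.50 ± 0.49 and Pax6, a neural progenitor factor, by 5.32 ± 0.59. Of 18 ERK target genes 4 fell and 0 rose, 8 when adjusted over the list alone (camera adjusted p = 9.65e-06; adjusted p = 0.491 with an estimated correlation), including Myc at -5.19 ± 0.78, Etv5 at -5.14 ± 0.99 and Etv4 at -4.44 ± 0.86. Of 38 fibroblast and mesenchyme genes 3 fell and 0 rose, 3 when adjusted over the list alone (camera adjusted p = 0.000845; adjusted p = 0.972 with an estimated correlation). Its collagens Col3a1 (-5.26 ± 2.53, adjusted p = 0.328) and Col1a2 (-4.95 ± 2.61, adjusted p = 0.383) did not pass singly. Of 13 Hox genes 2 fell, also when adjusted over the list alone (camera adjusted p = 0.00038; adjusted p = 0.972 with an estimated correlation), namely Hoxd8 at -4.63 ± 0.69 and Hoxd9 at -2.47 ± 0.53. Of 22 epithelial junction and keratin genes 0 passed, also when adjusted over the list alone, while the list passed downward (camera adjusted p = 0.00955; adjusted p = 0.972 with an estimated correlation), with Krt19 at -4.94 ± 1.45 (adjusted p = 0.0793). Of 17 naive and core pluripotency genes only Klf2 fell, and 3 when adjusted over the list alone (camera adjusted p = 0.0402; adjusted p = 0.972 with an estimated correlation). The median level of the epithelial list was 4.28 in A1, 4.24 in A2, 4.30 in REF1 and 7.93 in REF2. That of the pluripotency list was 5.63, 5.61, 4.74 and 9.18 in that order, so only REF2 stood well above iPS for either list. Klf5 stood at -4.35 ± 1.38 (adjusted p = 0.104), Esrrb at -2.47 ± 1.78 (adjusted p = 0.544) and Klf4 at -2.08 ± 0.57 (adjusted p = 0.0581). Sox2 differed by 1.65 ± 2.19 (adjusted p = 0.78), with 3 of 4 probe sets of the same sign. With an estimated correlation on line means 0 of the 6 list calls held. The estimate was -0.047 for the neural and 0.017 for the ERK list, with an unadjusted camera p of 0.00451 and 0.0285. A high correlation among genes therefore does not account for the loss of these 2 calls.

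The other lists did not pass in iPS against EF. Their camera adjusted p was 0.0564 for interferon and antigen presentation, 0.115 for imprinted genes, 0.326 for cell cycle and DNA replication, 0.331 for reprogramming factors, 0.372 for germline and meiosis and 0.413 for primitive endoderm and endoderm. It was 0.452 for primed pluripotency, 0.494 for glycolysis, 0.494 for macrophage and blood, 0.494 for skeletal and cardiac muscle, 0.62 for CDK inhibitors and p53 targets and 0.732 for DNA methylation and chromatin regulators. It was 0.734 for Wnt and GSK3 inhibition targets, 0.742 for cartilage and bone, 0.746 for trophoblast, 0.843 for endothelial and 0.907 for primitive streak and mesoderm genes. The median, mean and test of the reprogramming, primitive streak, trophoblast, endothelial and cartilage lists did not all share a sign.

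The fit with each line's 2 arrays averaged first called 292 genes, 229 higher and 63 lower in iPS. It did not call Ccn2, Klf2, Gap43, Gask1b, Tmem30b, Myof, H19, Myc, Etv4, Etv5 or Hoxd9. On simulated arrays of this comparison 54.4% of the calls of the block fit (156 of 287) were false against 2.78% (2 of 72) for line means. Only 50 genes were changed there at each size, so these are not the shares of false calls among the genes called in the data. The count of the block fit was 75 without line A1, 77 without A2, 848 without DAC8 and 874 without DAC2.

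An alternative added after the data were seen left out the arrays labelled DAC8 and REF2, so that iPS was compared with REF1 alone (4 arrays against 2). Lower in iPS were then Ccn2 at -10.41 ± 0.22, Postn at -10.19 ± 0.11, Tnc, which encodes tenascin C, at -10.06 ± 0.08, Col3a1 at -9.54 ± 0.14 and Tagln, a smooth muscle actin-binding protein, at -9.00 ± 0.15. Igfbpl1 was higher by 9.64 ± 0.07, Plekhh1 by 8.34 ± 0.08, Cnpy1 by 8.02 ± 0.05 and En2, a midbrain and hindbrain patterning factor, by 7.11 ± 0.12. Sox2 was higher by 5.50 ± 0.10 and Sall4 by 4.69 ± 0.11. The 5 lower genes lay below 5 in all iPS arrays and the 6 higher ones below 5 in REF1, so these sizes are lower bounds at best. Of 38 fibroblast genes 33 fell and 2 rose (camera adjusted p = 1.98e-42; adjusted p = 0.0164 with an estimated correlation). Of 34 cell cycle and DNA replication genes 33 rose (camera adjusted p = 5.66e-07; adjusted p = 0.143 with an estimated correlation), with Chek1 at 2.29 ± 0.06 and Top2a at 1.88 ± 0.05. Of 19 glycolysis genes 16 rose (camera adjusted p = 0.00787; adjusted p = 0.577 with an estimated correlation), with the glucose transporters Slc2a3 at 2.94 ± 0.05 and Slc2a1 at 2.77 ± 0.06. Epcam and Cdh1 lay below 5 in both iPS and REF1, so no direction was read for them. The epithelial (camera adjusted p = 0.784) and pluripotency lists (0.21, upward) no longer passed. In this setting 8669 genes differed, 3425 of them at least 2-fold, but 1 culture stood for all fibroblasts, so the fit compared lines rather than cell types. The correlation within lines was -0.0958 here against 0.966 with all 12 arrays, so the block narrowed the errors, and the share of false calls was not simulated for iPS against REF1.

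**Figure D3:**
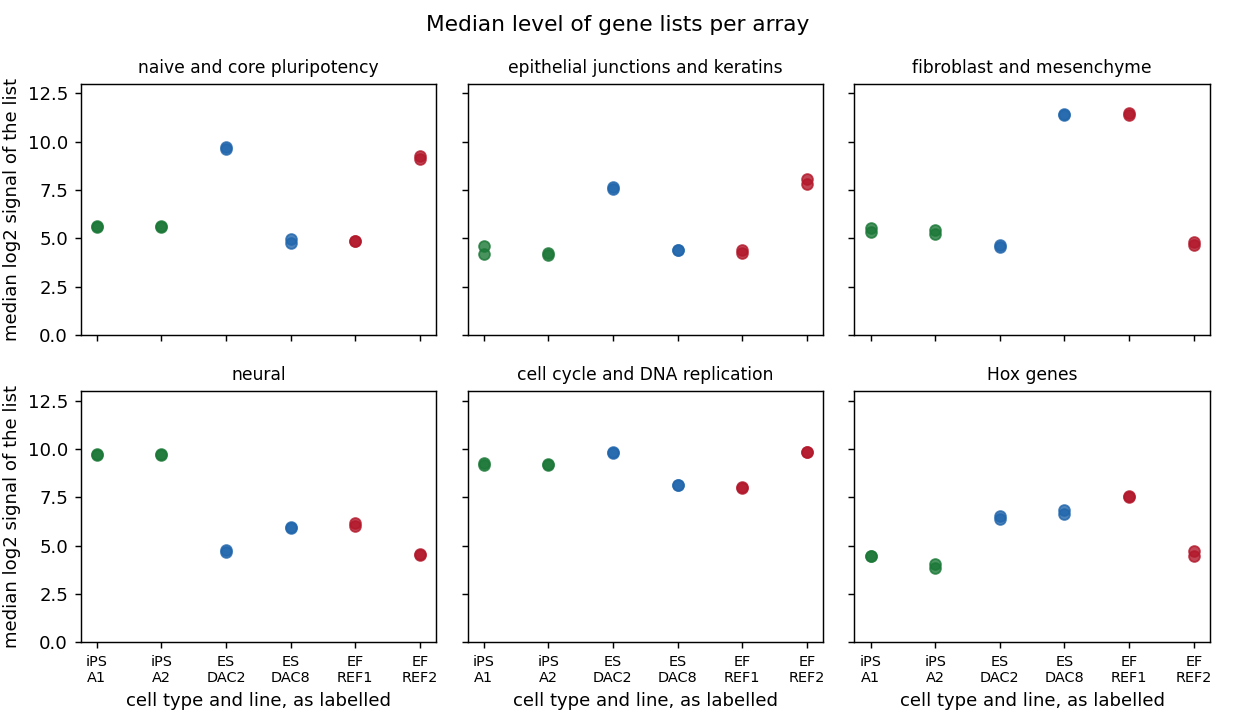
Median log2 signal of 6 gene lists per array (points, 2 per line), with cell types as labelled. The neural list stands at 9.70 and 9.72 in A1 and A2 and at 4.70 in DAC2, and the fibroblast list stands at 11.44 in the arrays labelled DAC8 and 11.43 in REF1 but at 4.73 in REF2.

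The comparison of iPS with ES arrays is the one the series was designed for, asking whether the iPS lines resembled ES cells in expression. Tal1 was again higher in the arrays labelled iPS, by 7.56 ± 0.55 (log2 difference ± SE, 4 arrays against 4, limma adjusted p = 3.5e-05), Rtn1 by 7.17 ± 0.56, Fez1 by 7.15 ± 0.56 and Elavl4 by 6.85 ± 0.56. Ccn2 stood at -8.29 ± 1.48, Klf2 at -7.32 ± 0.81 and Etv5, an ETS factor induced by ERK signalling, at -5.62 ± 0.99. Stra6l differed by 6.83 ± 0.78, Draxin by 6.75 ± 0.67, the cytokine Il18 by 6.67 ± 0.76, Tagln3 by 6.65 ± 0.69, Mgst1 by 6.59 ± 0.61 and Gap43 by 6.54 ± 1.39. Gask1b stood at -6.23 ± 0.88, Anxa3 at -6.19 ± 0.60, Tmem30b at -5.77 ± 0.89, Eci3 at -5.50 ± 0.73, Myof at -5.48 ± 1.28, Hoxa9 at -5.31 ± 1.29 and Cdh22 at -5.24 ± 0.79. Tal1, Fez1, Elavl4, Stra6l, Draxin and Tagln3 lay below 5 in all ES arrays and every lower gene in all iPS arrays. For Gap43 and Cdh22, 1 of 2 probe sets again went the other way. In all, 509 of 10510 genes differed, 325 higher and 184 lower in iPS, all 509 at least 2-fold. Of these, 287 of the 325 higher and 166 of the 184 lower were also called at least 2-fold in iPS against EF. Both comparisons used the same 4 iPS arrays, each against a mean of 1 line of either profile. Genes and lists found in both are therefore not separate findings.

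Of the 17 tested neural genes 12 rose in iPS against ES and 0 fell, 14 when adjusted over the list alone (camera adjusted p = 1.04e-28; adjusted p = 0.158 with an estimated correlation), including Map2, a dendritic microtubule protein, at 5.47 ± 1.11 and Neurog1 at 5.39 ± 0.49. Of 18 ERK targets 5 fell, and 9 fell and 1 rose when adjusted over the list alone (camera adjusted p = 1.51e-06; adjusted p = 0.491 with an estimated correlation). Of 13 Hox genes 3 fell, 6 when adjusted over the list alone (camera adjusted p = 5.36e-06; adjusted p = 0.972 with an estimated correlation). Of 38 fibroblast genes 2 fell (camera adjusted p = 0.00708), of 22 epithelial genes 1 (camera adjusted p = 0.00809) and of 17 pluripotency genes 2 (camera adjusted p = 0.0156), with the same counts when adjusted over each list alone and an adjusted p of 0.972 for each with an estimated correlation. The 2 pluripotency genes were Klf2 and Klf4 (-2.86 ± 0.57, adjusted p = 0.0127). Myc stood at -4.25 ± 0.78 (adjusted p = 0.00852), and Sox2 differed by 1.24 ± 2.19 (adjusted p = 0.858). The other lists did not pass, from 0.105 for interferon and antigen presentation to 0.994 for endothelial and primitive streak genes, and the primitive streak, trophoblast and endothelial lists had a median, mean and test of mixed sign.

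Line means gave 259 calls, 206 higher and 53 lower in iPS, without Ccn2, Klf2, Klf4, Gap43, Il18, Gask1b, Tmem30b, Etv5, Etv4, Myof, Hoxa9, Cdh22, Myc and Map2, and Hoxa9 also lost its call without any 1 array other than A1 replicate 2 (adjusted p = 0.0491 without it and up to 0.0581 without the others). The count was 74 without line A1 and 60 without A2, and neither fit was simulated for this comparison with all 12 arrays.

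Without the arrays labelled DAC8 and REF2, iPS was compared with DAC2 alone (4 arrays against 2). Lower in iPS were then Gpx2, a glutathione peroxidase of epithelial cells, at -9.61 ± 0.09, Klf2 at -8.20 ± 0.20, Epcam at -8.15 ± 0.18, Cdh1, which encodes E-cadherin, at -7.41 ± 0.24, Klf5 at -6.48 ± 0.14 and Esrrb at -5.49 ± 0.07. Gap43 was higher by 8.91 ± 0.08, the cyclin gene Ccnd2 by 8.05 ± 0.07, the intermediate filament gene Vim by 7.63 ± 0.05 and Map2 by 7.25 ± 0.06. The lower genes other than Klf5 lay below 5 in all iPS arrays and the 4 higher ones below 5 in DAC2. Sox2 stood at -2.11 ± 0.10, the opposite sign to the fit of all 12 arrays. Of 17 pluripotency genes 14 fell and 1 rose (camera adjusted p = 1.87e-07), and of 22 epithelial genes 21 fell (camera adjusted p = 9.69e-06), with an adjusted p of 0.143 for each with an estimated correlation. Of 17 neural genes 14 rose (camera adjusted p = 2.69e-25; adjusted p = 0.0708 with an estimated correlation). Of 38 fibroblast genes 17 rose and 13 fell (camera adjusted p = 0.000618, upward; adjusted p = 0.482 with an estimated correlation). The Hox list no longer passed (camera adjusted p = 0.0686), although its median level stayed lower in A1 (4.51) and A2 (3.94) than in DAC2 (6.44). In this setting, with the same correlation of -0.0958 within lines, 8626 genes differed, 3139 at least 2-fold. On simulated arrays of it 54.8% of calls (235 of 429) were false. Only 50 genes were changed there at each size, so that share does not carry over to the 8626 calls. It was far above the 0.05 that the adjustment aims at, so the fit of this setting called too readily on simulated arrays.

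The comparison of ES with EF arrays was to set the scale between pluripotent cells and fibroblasts. It gave no gene at adjusted p under 0.05 with limma (21 at unadjusted p under 0.05), 0 genes with line means and 6 with arrays taken as independent, since each label held a line of either profile. Col6a3, a microfibrillar collagen, stood at -2.51 ± 1.36, H19 at -2.51 ± 0.74, Hoxa9 at 2.94 ± 1.29, Hoxa10 at 2.90 ± 1.32 and Sox2 at 0.42 ± 2.19, each with an adjusted p of 1. Imprinted genes (camera adjusted p = 0.00114) and fibroblast genes (0.0156) passed downward with 0 of 19 and 0 of 38 members called, also when adjusted over the list alone, and Hox genes passed upward (0.00444) with 0 of 13 called. With an estimated correlation the adjusted p was 0.972 for all 3. The median of the Hox list (-0.09) and its mean (0.61) differed in sign, and the epithelial, trophoblast, ERK and chromatin lists, which did not pass, also had mixed signs. At the preset correlation, the camera adjusted p of the other lists lay between 0.248 for the cell cycle list and 0.994 for the epithelial list.

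Without the arrays labelled DAC8 and REF2, DAC2 stood against REF1 (2 arrays against 2). Tdh, a threonine dehydrogenase of mouse ES cells, was higher in DAC2 by 9.05 ± 0.14, Epcam by 8.84 ± 0.20, Cdh1 by 8.37 ± 0.28 and Sox2 by 7.61 ± 0.11. The BMP antagonist Grem1 stood at -10.00 ± 0.46, Postn at -9.94 ± 0.12, Tnc at -9.84 ± 0.09 and Lox, a collagen cross-linking enzyme, at -9.84 ± 0.22, and each of these 8 genes lay below 5 on its lower side. Of 17 pluripotency genes 16 rose (camera adjusted p = 8.79e-08; adjusted p = 0.143 with an estimated correlation) and of 22 epithelial genes 22 rose (camera adjusted p = 0.00218; adjusted p = 0.17 with an estimated correlation). Of 38 fibroblast genes 37 fell (camera adjusted p = 4.32e-49; adjusted p = 0.0164 with an estimated correlation). This setting called 8838 genes, 4235 at least 2-fold, and 2 genes were called when only line DAC8 was left out. Each side was 1 line, so lines rather than cell types were compared, with the same correlation of -0.0958 within lines. False calls were not simulated for DAC2 against REF1, and were 54.8% of simulated calls for iPS against DAC2 in this setting. Few genes were changed in that simulation, so no share of false calls is read from it for the 8838 genes. The Hox list turned downward without passing (camera adjusted p = 0.158).

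Lines of the same label were compared as the background for the cell types. A1 and A2 were close: 204 genes differed, 145 higher and 59 lower in A1, and 22 differed at least 2-fold. Higher in A1 were Gpat2 (2.70 ± 0.21, log2 difference ± SE, 2 arrays against 2), the heat shock gene Hspa1a (2.65 ± 0.09), Hoxa9 (2.23 ± 0.08) and the immediate early genes Egr1 (2.06 ± 0.12) and Fos (1.90 ± 0.08, 1 of 2 probe sets of that sign). Lower were the interferon lambda receptor Ifnlr1 (-2.11 ± 0.15), Rhox9 (-1.26 ± 0.20), Scn4b (-1.25 ± 0.11), Cldn11 (-1.25 ± 0.19) and Coch (-1.15 ± 0.14). Gpat2 lay below 5 in A2, and Ifnlr1, Scn4b and Coch in A1, so these 4 differences are lower bounds at best. Of 18 ERK targets 8 rose and 0 fell in A1, 11 when adjusted over the list alone (camera adjusted p = 1.04e-41; adjusted p = 0.00356 with an estimated correlation). Of 13 Hox genes 4 rose (camera adjusted p = 5.72e-19) and of 19 glycolysis genes 4 rose (camera adjusted p = 1.69e-07), each with an adjusted p of 0.137 with an estimated correlation. Of the 4 Hox genes, Hoxa9, Hoxa10 and Hoxa5 lay below 5 in both lines, where signal was not shown to be above background. Epithelial genes (camera adjusted p = 0.0153, upward; adjusted p = 0.411 with an estimated correlation) and interferon genes (camera adjusted p = 0.0185, downward; adjusted p = 0.479 with an estimated correlation) also passed, and testing lists between lines was added after the data were seen. The median of the interferon list (0.02) and its mean (-0.05) differed in sign. The epithelial list level was 4.63 in A1 replicate 1 but 4.21 in A1 replicate 2, against 4.16 and 4.23 in A2. Without A1 replicate 1, A1 replicate 2, A2 replicate 1 or A2 replicate 2 the count was 110, 96, 78 or 104, and Cldn11 (adjusted p up to 0.0702) and Rhox9 (adjusted p up to 0.0916) each lost their call, Cldn11 without A1 replicate 1, A1 replicate 2 or A2 replicate 2 and Rhox9 without A1 replicate 1 or A2 replicate 2. In simulated arrays of this comparison 5.31% of calls (11 of 207) were false.

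DAC2 and DAC8, both labelled ES, differed at 8872 of 10510 genes, 4157 of them at least 2-fold. Gpx2 was higher in DAC2 by 9.16 ± 0.12 (limma adjusted p = 1.25e-11), Epcam by 8.99 ± 0.18 and Tdh by 8.81 ± 0.10, while Grem1 stood at -10.11 ± 0.30, Tnc at -9.97 ± 0.09 and Postn at -9.82 ± 0.12. REF1 and REF2, both labelled EF, differed at 8800 genes, 4147 at least 2-fold, with Postn higher in REF1 by 10.29 ± 0.12 and Lox by 9.98 ± 0.10 and Tdh at -9.49 ± 0.10, Gpx2 at -9.03 ± 0.12 and Cdh1 at -8.30 ± 0.17, each below 5 on its lower side. Fibroblast genes fell in DAC2 against DAC8 (36 of 38, camera adjusted p = 1.52e-42) and rose in REF1 against REF2 (37 of 38, camera adjusted p = 8e-46), each with an adjusted p of 0.00315 with an estimated correlation. By contrast, 2 pairs of different label differed far less at 2-fold: 130 genes between DAC8 and REF1 (2136 called) and 410 between DAC2 and REF2 (4990 called). The other pairs of ES and EF lines did not, with 4238 genes between DAC2 and REF1 and 4101 between DAC8 and REF2. A1 or A2 against an ES or EF line gave 3140 to 3430. The pairs of different label were added after the data were seen.

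Sex chromosome genes were measured as a check of the lines. Xist, the RNA of the inactive X chromosome, measured 10.26 ± 0.04 in the arrays labelled DAC8, 10.44 ± 0.06 in REF1, 4.95 ± 0.10 in REF2, 2.81 ± 0.22 in DAC2 and 2.33 to 2.40 in the iPS lines. The Y-linked gene Eif2s3y measured 10.45 ± 0.08 in A1, 10.43 ± 0.27 in A2, 10.70 ± 0.05 in REF2, 8.97 ± 0.07 in DAC8, 8.91 ± 0.06 in REF1 and 2.52 ± 0.14 in DAC2. Uty measured 7.58 to 9.31 in all 6 lines and was highest in DAC2, where Eif2s3y lay below 5. Its level was therefore not read as a sign of a Y chromosome.

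The last comparisons placed the iPS lines between fibroblasts and ES cells. The changes of iPS against EF and of ES against EF correlated at Pearson r = 0.149 across genes (Spearman rho = 0.192, covariance 0.0519). Simulated unchanged groups against shared controls gave 0.498 ± 0.0204 (mean ± SD of 100 simulations, covariance 0.547). The simulation gave all 3 cell types the same spread between lines. In the data the median absolute log2 difference was 0.0783 between A1 and A2, 0.772 between DAC2 and DAC8 and 0.752 between REF1 and REF2. The 0.498 is therefore no reference for these arrays. With the controls split by culture r was -0.546 and -0.507, and leaving out REF1, REF2 or DAC2 gave 0.580, 0.617 or -0.0164. Without the arrays labelled DAC8 and REF2 it was 0.617 with a covariance of 1.76, against a simulated r of 0.579 and covariance of 0.0194. That simulation gave every line the spread between A1 and A2. The median absolute log2 difference was larger between DAC2 and REF2 (0.221) and between DAC8 and REF1 (0.133). The 0.579 is therefore no firm reference either. On the axis from fibroblasts at 0 to ES cells at 1, the iPS arrays lay at 0.533 ± 0.00299 (SD, n = 4), held-out ES arrays at 0.275 ± 0.114 and held-out EF arrays at 0.736 ± 0.0947, an order opposite to the labels. The axis from REF2 to DAC8 ran against that from REF1 to DAC2, so positions on these 2 average near the middle whatever the cells are, and the other 2 axes were short (0.294 and 0.471 per gene against 1.83 and 1.80), so 0.533 does not place the iPS arrays. On the single axis from REF1 to DAC2, added after the data were seen, A1 and A2 both lay at 0.526 and 0.671 and 0.679 axis lengths off it, the arrays labelled DAC8 at 0.0187 and those labelled REF2 at 0.955. No gene was called at least 2-fold in ES against EF, so 0 genes could be counted as left nearer the fibroblast level. With DAC2 and REF1 alone, 4235 genes separated them. At 3189 of these iPS was called on the REF1 side of DAC2, nearer to REF1 than to DAC2 at 2024 of the 3189, while 457 were not called and 589 lay beyond DAC2. Both the 3189 and the 2024 include genes beyond REF1, such as Klf2 at 3.47 to 4.30 in iPS against 9.83 and 9.78 in REF1. Neither is therefore a count of genes left at a fibroblast level. With 2 lines per type no exact permutation of lines could pass 0.05.

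**Figure D4:**
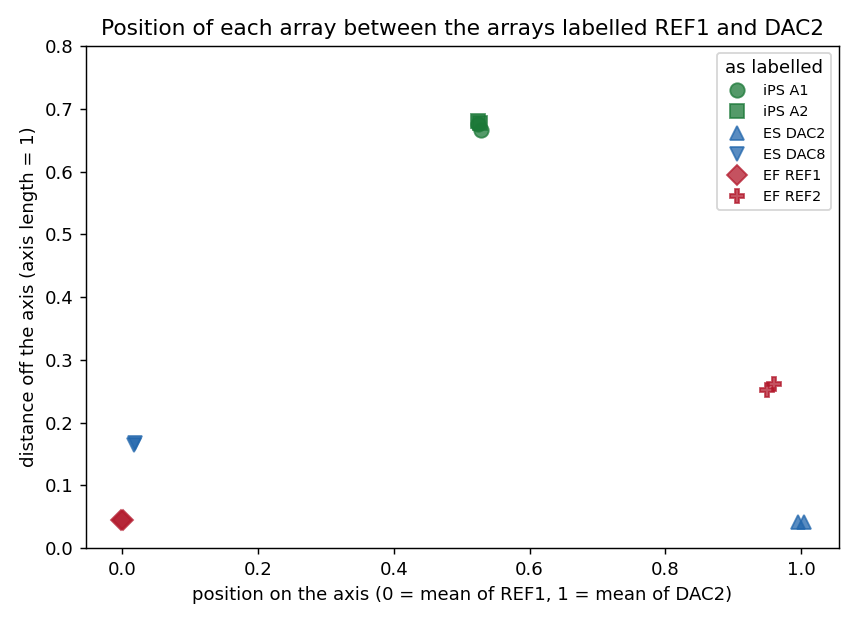
Position of each array on the axis from the mean of the arrays labelled REF1 (0) to the mean of those labelled DAC2 (1), against the distance off that axis in axis lengths, over the tested genes. The arrays labelled DAC8 lie near REF1 at 0.0187, those labelled REF2 near DAC2 at 0.955, and A1 and A2 lie at 0.526 with a distance of about 0.671 off the axis.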

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

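The choice of this test, the gap of 1 array to the nearest of the other 3 as a share of the range of its cell type, did not depend on the values, and no further test of these 5 results was made. The epithelial list level in iPS had a gap share of 0.859, with A1 replicate 1 at 4.63 and the others between 4.16 and 4.23. Dab2 in iPS had a share of 0.886, with A1 replicate 1 at 2.74 and the others between 2.96 and 2.99. Hoxd9 in ES had a share of 0.875, with DAC2 replicate 1 at 6.51 and the others between 6.37 and 6.39. Col6a3 in ES had a share of 0.847, with DAC8 replicate 1 at 5.10 and the others between 4.53 and 4.62. Cldn11 in ES had a share of 0.849, with DAC2 replicate 1 at 3.45 and the others between 3.95 and 4.04. These were 1 of 84 list and summary values and 4 of 324 gene values, but the usual chance rate of 1 in 20 cannot be read against them, since ES and EF each hold 2 pairs of near-identical arrays, which keeps most gaps small.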

How the results depend on the processing

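Leaving out the arrays labelled DAC8 and REF2 and the single axis from REF1 to DAC2 were chosen after the results were seen, and the other settings here were planned. Of 5189 values of named genes under an alternative, 4779 kept their direction and side of the threshold, 181 lost a call, 185 gained one and 44 turned sign, of which 35 were called on neither side. Of 342 list values 254 kept both, 24 lost a call, 15 gained one and 49 turned direction, of which 41 were called on neither side. With 1 array left out, 2250 of 2304 gene values kept both and 0 turned sign, where a line left with 1 array was assumed to vary like the others. Quantile normalization and equal medians changed 1 call each among 192 and 190 values of named genes, while the number of genes called in A1 against A2 went from 204 to 305 and 189, and in iPS against EF from 562 to 589 and 554. Leaving out lines or arrays means fewer samples, and no filter or every probe set means other numbers of tests; otherwise the cause was not tested. At a filter of 6 the primitive streak list gave no value. Signal near background limits dim genes, such as Cdh1, Epcam, Esrrb and Pecam1 in iPS against REF1, whose levels below 5 give no direction, since RMA gives them no detection call.

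The replicate numbers did not pair the arrays across all lines: the correlation of same-numbered arrays over the 15 pairs of lines ranged from -0.0804 to 0.242. It was over 0.1 in 3 pairs, A1 with A2 (0.177), REF1 with REF2 (0.145) and REF2 with DAC2 (0.242). A shared effect of replicate number within these pairs was not excluded. With a replicate block 502, 0 and 478 genes were called for iPS against EF, ES against EF and iPS against ES, and 194, 8897 and 8805 for A1 against A2, DAC2 against DAC8 and REF1 against REF2.

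In counts of genes called, iPS against EF gave 292 with line means, 3143 with no line block, 969 with no filter, 1137 with every probe set, 75 without line A1, 77 without A2, 848 without DAC8, 874 without DAC2 and 8669 without the arrays labelled DAC8 and REF2. For iPS against ES these were 259 with line means, 3007 with no line block, 890 with no filter, 1056 with every probe set, 74 without A1, 60 without A2 and 8626 without the arrays labelled DAC8 and REF2. ES against EF gave 6 with no line block, 2 without DAC8 and 8838 without the arrays labelled DAC8 and REF2. A1 against A2 gave 357 with an intensity trend and 78 to 176 with 1 array left out. With every probe set DAC2 against DAC8 gave 15412 and REF1 against REF2 gave 15239.

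The correlation of changes was -0.546 and -0.507 with the controls split, 0.0580 to 0.297 with 1 array left out, -0.0164 without DAC2, 0.580 without REF1, 0.617 without REF2 and 0.617 without the arrays labelled DAC8 and REF2. The position of iPS was 0.517 with no filter, 0.513 to 0.552 with 1 array left out, 0.522 without DAC8, 0.544 without DAC2, 0.498 without REF1, 0.568 without REF2 and 0.526 both on the single axis and without the arrays labelled DAC8 and REF2. Genes closer to EF than to ES, a count that also takes in genes beyond the EF level, numbered 2 without DAC8 and 2024 without the arrays labelled DAC8 and REF2.

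With an estimated correlation on line means, the list calls of all 3 comparisons were lost: adjusted p was 0.158 for neural and 0.491 for ERK genes in both iPS comparisons. It was 0.972 for Hox and fibroblast genes in all 3, epithelial and pluripotency genes in both iPS comparisons and imprinted genes in ES against EF. Direction turned at 0.972, called on neither side, for primitive streak genes in both iPS comparisons, Wnt and endothelial genes in iPS against ES, and epithelial and blood genes in ES against EF. With ranks, the pluripotency calls were lost (0.11 against EF and 0.0897 against ES), as were Hox (0.485), fibroblast (0.0522) and imprinted genes (0.0578) in ES against EF, and interferon genes passed downward (0.0109 against EF, 0.0247 against ES; adjusted p = 0.972 for each with an estimated correlation). Direction turned with ranks for endothelial (0.806 and 0.634), primitive streak (0.863 and 0.769) and trophoblast genes (0.88 and 0.985) in iPS against EF and ES, and for epithelial (0.863) and trophoblast genes (0.93) in ES against EF. With no filter, Hox genes in ES against EF (0.0972) and pluripotency genes in iPS against EF (0.0713) lost their calls. Direction turned with no filter for endothelial (0.884 and 0.822) and primitive streak genes (0.822 and 0.724) in iPS against EF and ES, Wnt genes in iPS against ES (0.837), and germline (0.837) and blood genes (0.949) in ES against EF. At a filter of 6, imprinted genes passed downward in iPS against EF (0.0275; adjusted p = 0.972 with an estimated correlation at the filter of 5), and direction turned for Wnt genes (0.995 and 0.833), cartilage genes against EF (0.965) and trophoblast genes in ES against EF (0.621).

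Single genes turned sign, uncalled on both sides, when a line was left out. Without DAC2, iPS minus ES was 1.08 for Cdh1, 0.84 for Epcam, 0.25 for Krt18, 0.58 for Pecam1, -0.10 for Sox4 and 0.0328 for Tfcp2l1, and ES minus EF was 1.84 for Igf2, 0.81 for Lum, 0.50 for Myc, -2.93 for Sox2 and 0.10 for Tgfbi. Without DAC8, iPS minus ES was 0.47 for Igfbp3, -0.13 for Ldhb, -0.44 for Pdk1 and -2.11 for Sox2, and ES minus EF was -0.0015 for Hoxa5 and -0.50 for Plagl1. Without REF1, iPS minus EF was 0.0455 for Igfbp3, -0.58 for Ldhb, 0.0916 for Postn and -2.20 for Sox2, and ES minus EF was 2.55 for Igf2, -0.16 for Klf4, 1.88 for Lum, -3.44 for Sox2 and 0.20 for Tgfbi. Without REF2, iPS minus EF was 0.96 for Cdh1, 0.69 for Epcam, 0.24 for Esrrb, 0.93 for Pecam1 and 0.38 for Tfcp2l1, and ES minus EF was -1.62 for Hoxa5 and -1.35 for Plagl1.

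Without the arrays labelled DAC8 and REF2, signs turned for Cdh1 (0.96), Epcam (0.69), Esrrb (0.24), Pecam1 (0.93) and Tfcp2l1 (0.38) in iPS minus EF, for Igfbp3 (0.47), Ldhb (-0.13), Pdk1 (-0.44) and Sox2 (-2.11) in iPS minus ES, and for Hoxa5 (-2.73) and Plagl1 (-2.67) in ES minus EF. In iPS against EF, cell cycle (5.66e-07), glycolysis (0.00787) and chromatin genes (0.0382) then passed upward and imprinted (0.0037) and muscle genes (0.0112) downward, epithelial genes lost their call (0.784), and direction turned for pluripotency (0.21), reprogramming (0.288) and cartilage genes (0.244). With an estimated correlation these 5 calls were lost (adjusted p = 0.143, 0.577, 0.366, 0.266 and 0.467 in that order). In ES against EF, cell cycle (3.34e-10), pluripotency (8.79e-08) and reprogramming genes (0.00787) passed upward and CDK inhibitor genes downward (0.0109), all 4 lost with an estimated correlation (adjusted p = 0.143, 0.143, 0.467 and 0.366). Direction turned there, upward for epithelial (0.00218), chromatin (0.00288), glycolysis (0.00288), germline (0.135), interferon (0.245), trophoblast (0.125) and Wnt genes (0.399), and downward for muscle (0.0302), Hox (0.158), neural (0.279) and ERK genes (0.991). The epithelial, chromatin, glycolysis and muscle calls were lost with an estimated correlation (adjusted p = 0.17, 0.366, 0.565 and 0.635). In iPS against ES, Hox genes lost their call (0.0686), though their median level stayed lower in A1 (4.51) and A2 (3.94) than in DAC2 (6.44). Primed genes there passed upward (0.000313) and interferon (0.0208) and reprogramming genes (0.0368) downward. With an estimated correlation these 3 calls were lost (adjusted p = 0.635, 0.266 and 0.366), as were those of fibroblast (0.482) and cell cycle genes (0.414) named next. Direction turned there, upward for fibroblast (0.000618), CDK inhibitor (0.198), imprinted (0.312) and muscle genes (0.991), and downward for cell cycle (0.0269), chromatin (0.167), glycolysis (0.425), primitive streak (0.901), endothelial (0.991) and trophoblast genes (0.991).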

Other observations

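The tests of exchange, mixing and normalization were chosen after the results they bear on were seen, and the counts of other splits were planned. Several genes outside the neural list were also higher in the arrays labelled iPS, against EF and ES arrays averaged as labelled. Tek, an angiopoietin receptor of endothelial cells, differed from EF by 5.92 ± 0.95 (log2 difference ± SE, 4 arrays against 4, limma adjusted p = 0.00383), Col9a1, a cartilage collagen, by 5.54 ± 0.89 and Tfap2b, an AP-2 factor of neural crest, by 4.95 ± 0.76. The CDK inhibitor genes Cdkn1c, which is imprinted, and Cdkn2a differed by 3.23 ± 0.63 and 3.05 ± 0.70, and the glycolytic gene Pfkp by 2.22 ± 0.40. Gadd45b, a stress response gene, stood at -4.08 ± 0.59 and the imprinted RNA Meg3 at -3.65 ± 0.76. Cdkn1c, Cdkn2a, Pfkp, Gadd45b and Tek were not called on line means, and the lists holding these genes did not pass.

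The arrays labelled DAC8 carried a fibroblast profile and those labelled REF2 an ES-like one. Genes at least 32-fold higher in DAC2 than in REF1 gave an apparent ES share of 0.0106% in the arrays labelled DAC8 (median of 76 genes, quartiles -0.193 to 0.157), which argues against fibroblasts mixed into ES cells. Genes at least 32-fold higher in REF1 gave an apparent fibroblast share of 0.0296% in the arrays labelled REF2 (median of 236 genes, quartiles -0.0647 to 0.499), which argues against ES cells mixed into fibroblasts. Rank correlations, which a normalization alike for all genes of an array leaves unchanged, also placed the 4 arrays with the other type, by a margin of at least 0.334. Labels exchanged between an ES line and a fibroblast culture stay open as a hypothesis: all 4 of 4 arrays correlated best, outside their own line, with the line of the other type, but this restates the pattern and is no independent support.

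In the arrays labelled iPS, with high neural and low epithelial genes, 14 of 17 neural genes stood over 1 log2 unit above all 4 other lines in both A1 and A2, which a mix of ES-like cells and fibroblasts would not give. Genes at least 32-fold higher in DAC2 and REF2 than in DAC8 and REF1 gave an apparent ES-like share of 0.301% (median of 59 genes, 35 under 1%), with Epcam at 0.163% and Esrrb at 0.428%, which argues against an ES-like share of 10% or more, although 15 genes lay over 10%, among them Igfbpl1 at 428%, Plekhh1 at 207%, Cnpy1 at 176% and Sox2 at 22.4%, and the upper quartile was 9.66%. Cells of neural character are a candidate source, with Elavl4 at 10.70 and Neurog1 at 9.70 in A1. Of the 17 neural genes 9 lay at or above 5 in DAC2 or REF2 and 11 in DAC8 or REF1, 0 were in another list, and the labels state no sort. RNA of another sample under these labels, which mark the cells as positive for SSEA-1, Oct4, Nanog and Sox2, stays open, since the highest correlation of A1 or A2 with another line was 0.736, and a state of the iPS lines themselves stays open and untested.

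For iPS against EF, 1 of the 35 splits of the 8 arrays, the real one, gave as many as 562 genes, and the highest of the others gave 12. For iPS against ES, 1 of 35 gave as many as 509, and the highest of the others gave 4. Splits that part the near-identical arrays of a line were bound to call few genes, and only 3 of the 35 keep lines whole (highest other 0 in both), too few for a share under 0.05. For ES against EF the real count was 0, so 35 of 35 splits gave at least as many by construction and nothing about chance follows, and the split of DAC8 and REF1 against DAC2 and REF2 gave 7666, which points to a structure of the samples. This reading was adopted after the counts were seen: by the rule written beforehand, a share of all 35 splits under 0.05, chance would have been excluded for iPS against EF and iPS against ES and not for ES against EF.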
